A study of Homo sapiens with 6 samples.

How the data were processed

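The series profiled binding of E2F7 by chromatin immunoprecipitation and sequencing (ChIP-seq) in IMR90 cells, a human fetal lung fibroblast line. The labels list 6 samples: E2F7 ChIP from growing cells, from quiescent cells, from Ras-induced senescent cells with an RB hairpin and from Ras-induced senescent cells with an E2F7 hairpin, an IgG ChIP and an input. Each group holds 1 sample. Per the labels' protocols, cells carried an ER-Ras vector with hairpins and were collected 4 days after tamoxifen. The labels give no treatment for the growing and quiescent samples, and they give 10 µg of E2F7 antibody per ChIP. Peak lists of 3 samples were analysed here: growing, quiescent and senescent with RB knockdown. No peak list of the other 3 samples enters a comparison, though the caller's control library may be among these samples. No list of senescent cells with intact RB was analysed here.

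Reads were aligned with Bowtie to hg18, per the submitters' processing notes. The Bowtie version and settings are not given in the sources used here. Per the file headers, the authors called peaks with MACS 1.4.1 (build 20110627) on each library alone, against 1 control library common to all 3 lists. The headers do not state which labelled sample the control was. The p cutoff was 1e-05, the band width 300 bp, the model fold range 10 to 30, the effective genome size 2700000000 bp, and local background was taken over 1000 and 10000 bp. The caller kept at most 2 tags per position and scaled the smaller library to the larger. Tags were 36 bp long. The fragment length used by the caller (d) was 200 bp for the growing and quiescent lists and 125 bp for the RB knockdown list, which can change peak widths and peak numbers between lists. MACS 1.4 falls back on a preset d when it builds no fragment model, and the headers do not say whether 200 bp was estimated or preset.

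Per the file headers, each deposited peak carries a tag count, which is the number of ChIP tags in the peak. The deposited p-value is given as -10*log10 p against local background, 10 times the −log10 value. Fold enrichment is the authors' linear ratio of ChIP tags to the local background estimate. The false discovery rate (FDR) is a deposited percent from the caller's exchange of ChIP and control. Peak width and the summit's distance from the peak start are deposited in bp. These scores are the authors' values for each peak and were used only to describe, rank or filter peaks within a list, never as a change between lists. The exceptions are the FDR, fold enrichment, -10*log10 p, tags and widths, whose medians, and for tags the mean per peak, are set side by side as properties of each list.

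The headers give 25104368 tags for the growing ChIP library, of which 22628990 remained after the duplicate limit. They give 26392429 and 25212239 for the quiescent library, 26032124 and 23379790 for the RB knockdown library, and 22770173 and 22107968 for the control. Intervals for the share of tags in peaks are 95% Wilson intervals. Intervals for shares of peaks are 95% exact (Clopper-Pearson) binomial intervals. Both cover counting error only, since duplicate tags and neighbouring peaks are not independent.

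With 1 library per group there was no replicate error and no test between conditions, and every comparison is between libraries. Peaks of 2 lists were called shared when they overlapped by at least 1 bp. Chance overlap came from 1000 circular shifts of the second list along each chromosome (one-sided, smallest possible p 0.000999). The length of a chromosome was taken as the largest peak end in any list. Circular shifts keep peak number, width and clustering but not the tendency of peaks to lie in open or mappable chromatin, so they give a lower bound on chance overlap. Shifts of 10 to 100 kb served as the alternative. Regions were made by merging overlapping peaks of all 3 lists. Median fold enrichment of shared and unshared peaks within a list was compared by a two-sided permutation test over peaks (100000 resamples, smallest possible p 1e-05), with Benjamini-Hochberg adjustment over 6 ordered pairs of lists. All 3 lists share the control library. What a common control alone would add to their overlap was not estimated, because that needs reads not used here.

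The designs, alternatives and naming rule were fixed before the data were examined. The named items were the 10 regions in all 3 lists with the lowest sum of within-list ranks by -10*log10 p, and in each list the 5 peaks with the highest fold enrichment that overlapped no other list. Peaks on the Y chromosome were left out of the named regions. Alternatives were a -10*log10 p of at least 100, an FDR of at most 5%, a fold enrichment of at least 10, reciprocal overlap of at least 50%, summits within 200 bp, lists at the length of the shortest (9481 peaks), chromosomes 1 to 22 and X, other rankings and other measures of strength. The gene annotation at hand is for GRCh38 and not for hg18, so no gene was assigned to a peak, and the planned promoter and gene list tests were not run. Coordinates are hg18, 1-based, as the files give them. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0. On simulated data the overlap procedure recovered 2000 of 2000 placed shared peaks. These had been copied unchanged between the lists, so full recovery checks the code only. The procedure gave p under 0.05 for 1 of 20 unrelated pairs, and the median test did so for 2 of 40 unchanged groups. The unrelated peaks were placed at random and evenly over the sequence, so the shift p-values were not tested on clustered lists like the real ones.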

Results

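E2F7, an atypical member of the E2F family of transcription factors that represses E2F target genes, was mapped by ChIP-seq in IMR90 fetal lung fibroblasts. The series examined its binding in growing and in senescent cells with different hairpins. Peak lists were compared for growing cells, quiescent cells and Ras-induced senescent cells in which RB, the retinoblastoma protein, was knocked down. There was 1 library per state, so the values below describe these libraries and carry no replicate error. ChIP libraries held 22628990 (growing), 25212239 (quiescent) and 23379790 (RB knockdown) tags after the caller's duplicate limit.

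The first comparison was of how many E2F7 sites were called in each state. The list of senescent cells with RB knockdown held 43648 peaks over 33.6 Mb. The quiescent list held 10242 peaks over 13.3 Mb, and the growing list held 9481 peaks over 8.72 Mb. The RB knockdown list thus held 4.60 times as many peaks as the growing list and 4.26 times as many as the quiescent list. It covered 3.86 and 2.53 times as much sequence, with 1.03 and 0.927 times the filtered tags of these libraries. In the RB knockdown library 9.98% of filtered tags lay in peaks (95% Wilson interval 9.97% to 10.0%), against 2.75% (2.75% to 2.76%) in quiescent and 1.496% (1.491% to 1.501%) in growing cells. These shares depend on how much was called. Mean tags per peak in the RB knockdown list were 1.498 times those of the growing list and 0.790 times those of the quiescent list. Peaks had a median width of 650 bp with RB knockdown (quartiles 441 and 929), 1091 bp in quiescent cells and 711 bp in growing cells. The median peak held 38 tags in the RB knockdown list, 50 in the quiescent list and 23 in the growing list.

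The lists differed in the false discovery rate of their peaks. Median fold enrichment over local background was 7.13 in the RB knockdown list, 6.33 in the quiescent list and 6.56 in the growing list, and median -10*log10 p was 72.5, 71.5 and 60.1. The caller's median FDR was 1.21% in the RB knockdown list, 26.4% in the quiescent list and 72.6% in the growing list. An FDR of at most 5% was met by 42760 RB knockdown peaks (98.0%), 1823 quiescent peaks (17.8%) and 174 growing peaks (1.84%). At a fixed -10*log10 p of at least 100 the lists held 12473, 2795 and 833 peaks in the same order. In the growing list even the lower quartile of the FDR was 70.9%, and every count of growing peaks carries that limit. No test between states was possible with 1 library each.

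The next comparison asked how far the sites of the 3 states coincided. Of the quiescent peaks, 54.8% (95% exact interval 53.8% to 55.8%, 5613 of 10242) overlapped an RB knockdown peak. Of the growing peaks, 23.5% (22.6% to 24.4%, 2228 of 9481) overlapped an RB knockdown peak and 15.3% (14.5% to 15.99%, 1446 peaks) overlapped a quiescent peak. In the reverse direction, 14.1% of RB knockdown peaks lay in the quiescent list and 5.65% in the growing list. Of the quiescent peaks, 13.9% lay in the growing list. These shares depend on the threshold, and most growing peaks had a high FDR. With a -10*log10 p of at least 100 in both lists, 64.5% (61.1% to 67.7%) of growing peaks overlapped an RB knockdown peak and 47.3% (43.9% to 50.8%) a quiescent peak, and 62.0% (60.2% to 63.8%) of quiescent peaks overlapped an RB knockdown peak. An FDR of at most 5% in both lists left 174 growing and 1823 quiescent peaks, sets of unequal size. The values were then 95.4% (91.1% to 98.0%), 73.6% (66.4% to 79.9%) and 83.0% (81.2% to 84.7%). Among the full lists, circular shifts gave 3.02% for quiescent in RB knockdown, 2.599% for growing in RB knockdown and 0.825% for growing in quiescent. In this permutation test all 6 ordered pairs exceeded every one of 1000 shifts (one-sided p = 0.000999, the smallest the shifts can give). Shifts of 10 to 100 kb, which keep the neighbourhood, gave 6.24%, 5.05% and 1.81% for those 3 pairs, and the observed overlap again exceeded every shift. All lists were called against the same control library, and its contribution to the overlap was not estimated.

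**Figure D1:**
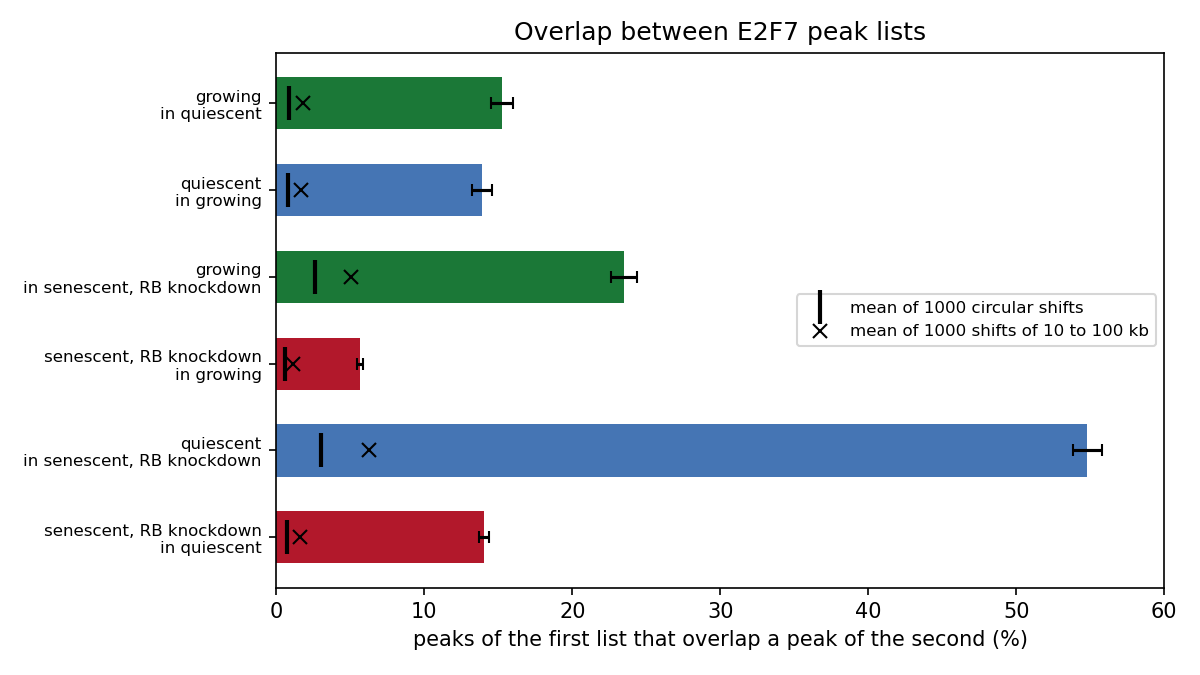
Bars show the percent of peaks of the first list that overlap a peak of the second by at least 1 bp, with 95% exact binomial intervals that cover counting error only. Vertical ticks mark the mean of 1000 circular shifts and crosses the mean of 1000 shifts of 10 to 100 kb. With every listed peak, quiescent in RB knockdown was the highest pair at 54.8%, and the other pairs lay between 5.65% and 23.5%. At an FDR of at most 5%, which left 174 growing and 1823 quiescent peaks, growing in RB knockdown was the highest pair. These sets are of unequal size.

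Lists of unequal length share unequal numbers of peaks, so each was also reduced to its 9481 strongest peaks by -10*log10 p. At that length 32.9% of quiescent peaks (32.0% to 33.9%) overlapped an RB knockdown peak. The growing list then shared 14.5% (13.8% to 15.3%) with the RB knockdown list and 14.8% (14.1% to 15.6%) with the quiescent list. Among the 500 strongest peaks per list the intervals of the 3 pairs overlapped. The shares there were 31.4% (27.4% to 35.7%) for quiescent with RB knockdown, 32.4% (28.3% to 36.7%) for growing with RB knockdown and 32.6% (28.5% to 36.9%) for growing with quiescent.

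Merging the 3 lists gave 54578 regions. Of these, 36381 (66.7%) were in the RB knockdown list alone, 7023 (12.9%) in the growing list alone and 4416 (8.09%) in the quiescent list alone. A further 4375 regions (8.02%) were shared by the quiescent and RB knockdown lists, 986 by the growing and RB knockdown lists, and 204 by the growing and quiescent lists. All 3 states had a peak in 1193 regions (2.19%). Absence from a list means that no peak passed that list's threshold, not that E2F7 was absent. When summits had to lie within 200 bp of each other, 593 growing peaks had a partner in both other lists, and with an FDR of at most 5% in every list 122 regions were common to all 3.

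The regions common to all 3 states that ranked first by -10*log10 p were long, and that ranking favours wide peaks. In each of the 10 leading regions each list had a peak of at least 3000 bp, and the merged regions ran from 3698 to 19433 bp. The first was chromosome 12, 123958916 to 123962613, where the growing peak had 567 tags and 9.87-fold enrichment, the quiescent peak 1521 tags and 23.8-fold, and the RB knockdown peak 3458 tags and 57.2-fold, each relative to its own local background. On chromosome 11 there were 3 of the regions. The region at 65020420 to 65033807 held the growing list's peak of lowest p, with 1817 tags, and an RB knockdown peak of 5250 tags. The region at 62036796 to 62056228 was the longest, with an RB knockdown peak of 5021 tags and 68.6-fold enrichment. The region at 64943891 to 64955480 had 7.38-fold enrichment in the growing list, 7.45-fold in the quiescent list and 10.9-fold in the RB knockdown list. Chromosome 6 held 2 of the regions, at 132308035 to 132315141 and at 33043295 to 33050373. In the former the summits of the 3 lists lay within 49 bp of each other, and in the latter within 55 bp.

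The remaining regions were on chromosome 8 (145054662 to 145066905), chromosome 16 (87025112 to 87043876), chromosome 17 (55269223 to 55279463) and chromosome 1 (85814294 to 85826581). On chromosome 17 the summits lay within 52 bp of each other, while on chromosome 16 they spread over 7375 bp. In 5 of the 10 regions the summits of all 3 lists lay within 200 bp. Across the 10 regions fold enrichment ranged from 5.94 to 17.04 in the growing list, from 7.45 to 23.8 in the quiescent list and from 10.9 to 68.6 in the RB knockdown list. The common control and the differing settings of d keep these ranges from being read as a change in binding. All 10 regions stayed in all 3 lists at an FDR of at most 5% and at a -10*log10 p of at least 100. Since they had been selected by -10*log10 p, this was no separate check. At a fold enrichment of at least 10 the regions on chromosome 12 and at 132308035 on chromosome 6 were left in 2 lists, and 4 others (at 64943891 on chromosome 11, on chromosomes 17 and 1, and at 33043295 on chromosome 6) in 1 list.

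**Figure D2:**
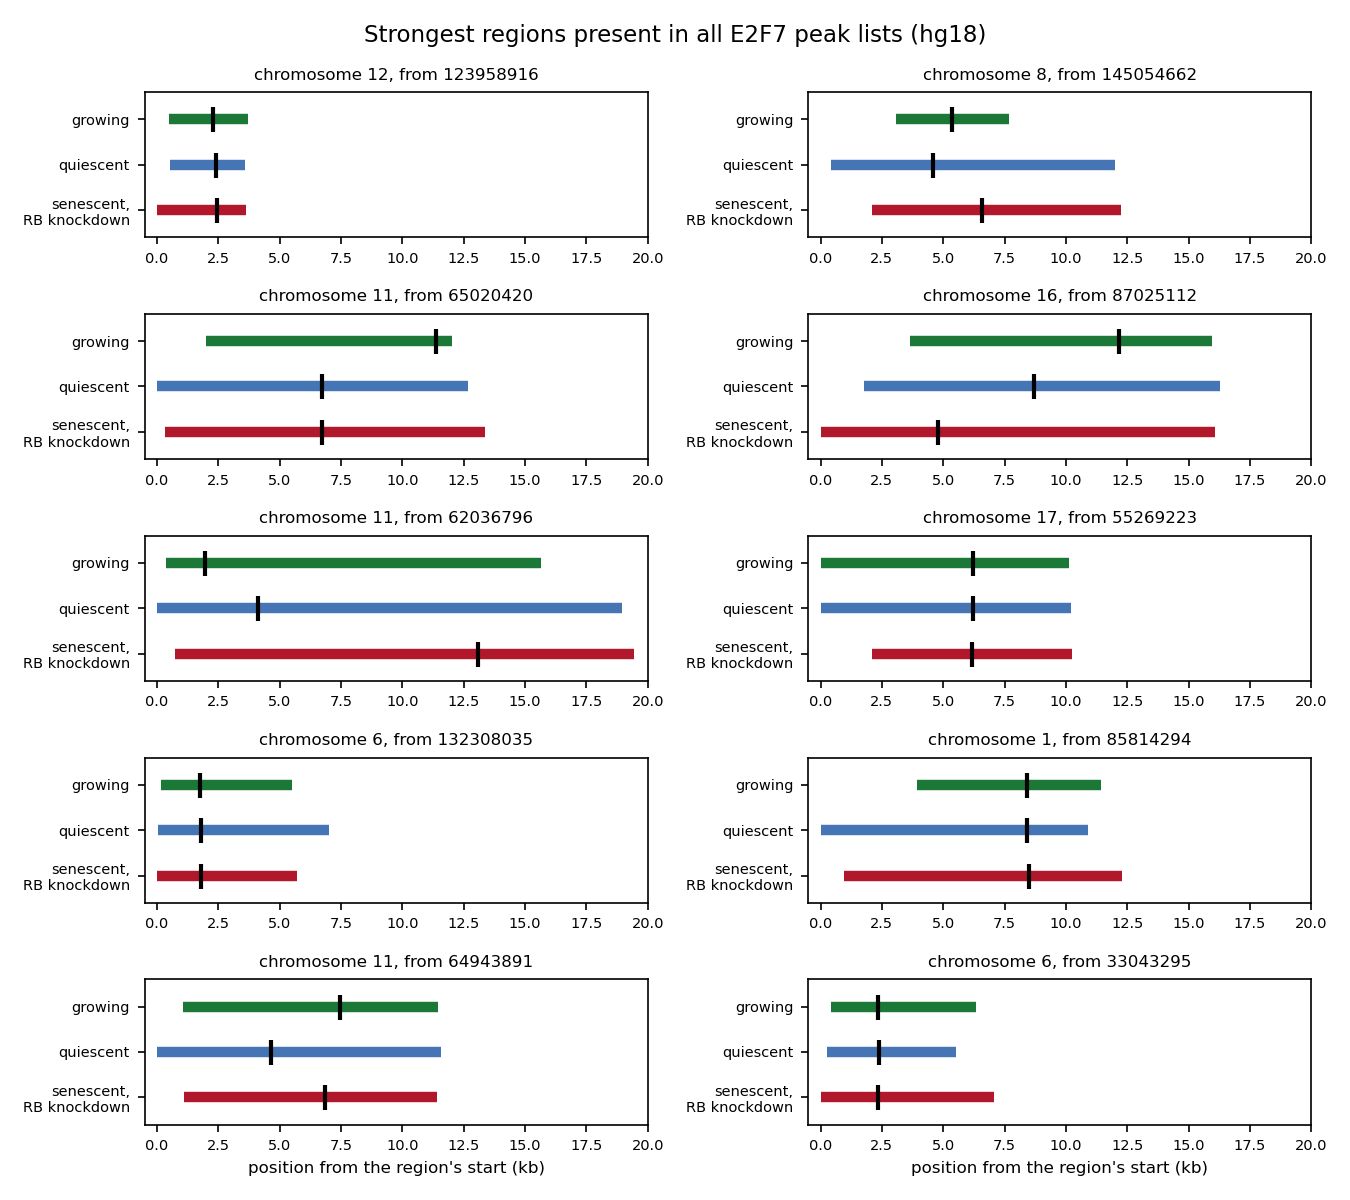
Each panel maps, to the same scale in kb from the start of the merged region (hg18), the strongest peak of each list in one of the 10 leading common regions. Coloured bars are peaks and black ticks are summits, which lie within 200 bp of each other in 5 of the 10 regions and spread over up to 11121 bp on chromosome 11.

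The tallest peaks called in 1 state alone were 621 to 1448 bp wide. They were ranked by fold enrichment, and the common regions by -10*log10 p, so the widths of the named peaks of both sets are not comparable. The tallest RB knockdown peak with no partner was on chromosome 7, 127903422 to 127904348, with 96 tags and 37.8-fold enrichment. The next 4 lay on chromosome 19 (5928932 to 5929762, 34.6-fold), chromosome 22 (49310355 to 49311802, 34.0-fold), chromosome 2 (202838317 to 202839222, 32.6-fold) and chromosome 17 (72832678 to 72833465, 32.6-fold), all with an FDR of 0%. The 5 tallest quiescent-only peaks had 19.9-fold to 20.5-fold enrichment and an FDR of at most 0.3%. They included a pair on chromosome 8, at 94149521 to 94150397 with 57 tags and at 94485379 to 94486378 with 60 tags. The others were on chromosome 7 (46021342 to 46022205), chromosome 6 (55666702 to 55668076) and chromosome 13 (77305449 to 77306330, 89 tags). The tallest growing-only peak, on chromosome 2 at 100369737 to 100370480, had 33 tags, 13.1-fold enrichment and an FDR of 21.4%. The other growing-only peaks, on chromosome 20 (17746969 to 17747776), chromosome 1 (44255829 to 44256755), chromosome 8 (41430609 to 41431262) and chromosome 7 (33732589 to 33733209), had 24 to 37 tags and FDRs from 21.3% to 78.0%.

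Within a list, peaks shared with another state were compared with the rest. In the RB knockdown list, peaks shared with the growing list had a median fold enrichment of 8.57 against 7.06 for the others, a difference of 1.51. Peaks shared with the quiescent list had 8.27 against 6.98, a difference of 1.29. In the quiescent list the difference was 0.69 for peaks shared with the growing list (6.95 against 6.26). All 3 differences had an adjusted p of 1.2e-05 in the permutation test over peaks. For quiescent peaks shared with the RB knockdown list it was 0.15 (6.41 against 6.26, adjusted permutation p = 0.00854), and it did not pass at a -10*log10 p of at least 100 (0.02, adjusted p = 0.92). In the growing list shared peaks had lower medians, by -0.70 for the quiescent list and -0.92 for the RB knockdown list (adjusted permutation p = 1.2e-05 for both). At a -10*log10 p of at least 100 these became -0.02 (adjusted permutation p = 0.92) and -0.88 (adjusted permutation p = 7.5e-05). At an FDR of at most 5% both were positive, 0.675 and 1.97, and neither passed (adjusted permutation p = 0.28 and 0.217). The growing peaks turned the other way on every other measure tried. Those shared with the RB knockdown list held a median of 55 tags against 20, and were 1284.5 bp wide against 650 bp. Tags, -10*log10 p and width are linked, and a wider peak more easily meets an overlap of at least 1 bp. These measures are therefore not separate evidence on strength. At a fold enrichment of at least 10 the fold difference was also positive, 1.05. Peaks of 1 library are not independent replicates, and these p-values describe the lists only.

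The distribution over chromosomes was compared next. Peaks of all 3 lists were dense on chromosomes 17 and 19, both known as gene-rich, and sparse on chromosomes 13 and X. On chromosome 19, which made up 2.07% of the sequence spanned, lay 5.22% of growing peaks (4.78% to 5.69%), 3.62% of quiescent peaks (3.27% to 4.00%) and 3.35% of RB knockdown peaks (3.19% to 3.53%). On chromosome 17 the shares were 6.25%, 4.74% and 4.63% against 2.56% of the sequence. On chromosome X, with 5.01% of the sequence, they were 3.14% (2.80% to 3.51%), 3.28% (2.94% to 3.64%) and 2.03% (1.895% to 2.16%). Chromosomes 16, 17, 19 and 22 together, a set picked after the lists were seen, held 18.7% (17.9% to 19.5%) of growing, 14.1% (13.4% to 14.8%) of quiescent and 12.9% (12.6% to 13.2%) of RB knockdown peaks. With a -10*log10 p of at least 100 these became 26.7%, 16.1% and 14.4%. Across the 22 autosomes, which are not replicates, the shares of peaks correlated with Pearson r = 0.98 between the quiescent and RB knockdown lists, 0.89 between growing and quiescent, and 0.89 between growing and RB knockdown. At a -10*log10 p of at least 100 these values were 0.97, 0.65 and 0.65. Shares of peaks follow chromosome size. With each share divided by the share of sequence the order turned, with r = 0.95 between growing and quiescent, 0.903 between growing and RB knockdown and 0.89 between quiescent and RB knockdown. The Y chromosome held 15 growing, 17 quiescent and 5 RB knockdown peaks, and there were 0 peaks on unplaced or mitochondrial sequence in any list. The Y calls were not examined further and are not taken as E2F7 binding on that chromosome. With chromosomes 1 to 22 and X alone, 15.2% of growing peaks lay in the quiescent list, against 15.3% in the full lists. The sequence spanned includes the Y chromosome, at 1.86%.

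**Figure D3:**
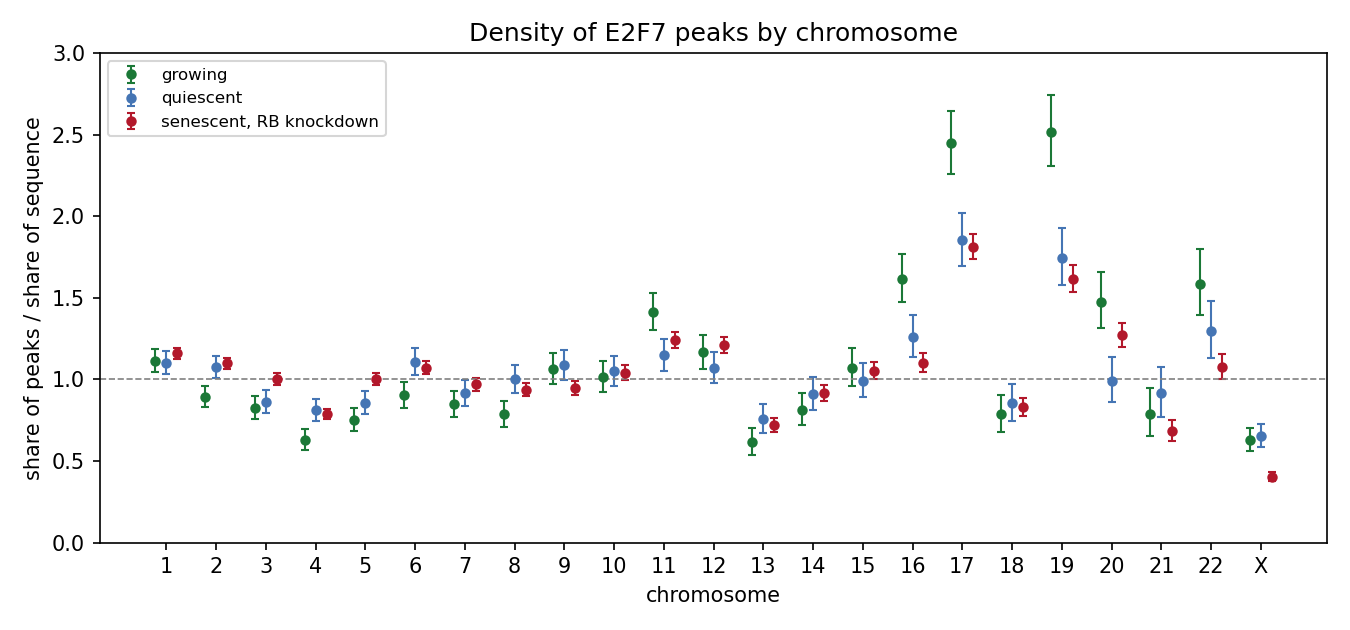
Points give each chromosome's share of a list's peaks divided by its share of the sequence spanned by the lists, with 95% exact binomial intervals that cover counting error only. The dashed line marks equal density. On chromosome 19 the ratio was 2.52 for growing, 1.75 for quiescent and 1.62 for RB knockdown peaks, and on chromosome X it was 0.627, 0.654 and 0.404.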

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

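The share of common peaks exceeded the shifts in all 6 ordered pairs under the 8 alternatives tried. The shifts of 10 to 100 kb were themselves 1 of these and were run on the full lists only, and the others used circular shifts. The shares themselves moved with the threshold, and so did the order of pairs. Growing in RB knockdown went from 23.5% to 64.5% at a -10*log10 p of at least 100, 95.4% at an FDR of at most 5% and 42.6% at a fold enrichment of at least 10. Growing in quiescent went from 15.3% to 47.3%, 73.6% and 25.9%, and quiescent in RB knockdown from 54.8% to 62.0%, 83.0% and 53.6%. The highest pair was therefore quiescent in RB knockdown for all listed peaks and at a fold enrichment of at least 10, and growing in RB knockdown at the other 2 thresholds. There the intervals overlapped at a -10*log10 p of at least 100 (61.1% to 67.7% against 60.2% to 63.8%) but not at an FDR of at most 5% (91.1% to 98.0% against 81.2% to 84.7%). The thresholds left sets of unequal size, 174 growing against 1823 quiescent peaks at that FDR. At equal numbers from each list, the full RB knockdown list held 98 of the 100 strongest peaks of either. Among the 500 strongest it held 85.8% of growing and 94.2% of quiescent peaks, so the order at that FDR was not seen there. In the reverse direction, RB knockdown in growing fell from 5.65% to 4.74%, 0.482% and 1.466%, RB knockdown in quiescent went from 14.1% to 14.9%, 4.14% and 8.18%, and quiescent in growing from 13.9% to 13.9%, 7.02% and 5.73%. Most other results moved with the threshold as well. At a -10*log10 p of at least 100 the growing, quiescent and RB knockdown lists held 833, 2795 and 12473 peaks over 1.58, 4.83 and 14.0 Mb, with 349 regions in all 3. At a fold enrichment of at least 10 they held 216, 943 and 6345 peaks over 0.253, 1.35 and 5.01 Mb, with 49 regions in all 3. At an FDR of at most 5% the growing and quiescent lists held 174 and 1823 peaks over 0.510 and 3.38 Mb, with 122 regions in all 3, while the RB knockdown list kept 42760 of its 43648 peaks. The number in all 3 lists was 751 with reciprocal overlap of at least 50% and 593 with summits within 200 bp, both counted as growing peaks rather than merged regions. At matched length, ranking by fold enrichment gave 11.6% of growing and 25.1% of quiescent peaks in the RB knockdown list, and ranking by tags gave 10.9% and 24.6%. The 500 strongest gave 32.6% (growing in quiescent), 32.4% (growing in RB knockdown) and 31.4% (quiescent in RB knockdown), and the 1000 strongest gave 28.7%, 28.3% and 34.2%. At a -10*log10 p of at least 100, the median fold difference between shared and unshared peaks was -0.02 for growing against quiescent and 0.02 for quiescent against RB knockdown, both short of the threshold (adjusted permutation p = 0.92). At an FDR of at most 5% it changed sign to 0.675 (growing, quiescent), 1.97 (growing, RB knockdown) and -0.22 (quiescent, RB knockdown), with adjusted permutation p of 0.28, 0.217 and 0.29. The growing list's differences also turned positive at a fold enrichment of at least 10 (1.35 for quiescent, 1.05 for RB knockdown). They were positive in tags (38 and 35), in -10*log10 p (23.3 and 16.3) and in width (651.5 and 634.5 bp). The cause was not tested. The share of peaks on chromosomes 16, 17, 19 and 22 at a -10*log10 p of at least 100 was 26.7% (growing), 16.1% (quiescent) and 14.4% (RB knockdown), and at an FDR of at most 5%, chosen after seeing the data, 32.2% (growing) and 16.9% (quiescent). The tests of promoters and gene lists were not run, because no annotation of hg18 was used here. No paired analysis was possible because each group holds 1 sample, and for the same reason no replicate could be left out. Filtered tags differed between the libraries by at most 1.11 times, while the median FDR ranged from 1.21% to 72.6%, so the growing list limits every comparison it enters.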

Other observations

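The leading E2F7 peaks are described here by both rankings, after the lists were seen. Ranked by -10*log10 p, which grows with tag number and so favours wide peaks, the 50 leading peaks had a median width of 2567 bp in growing, 3569.5 bp in quiescent and 3806 bp in RB knockdown cells. Of these, 22, 29 and 28 reached 3000 bp. Ranked by fold enrichment, the 50 leading peaks had medians of 1198.5, 1256.5 and 1294 bp. Both rankings had 16, 18 and 23 peaks in common, and the contrast in width follows from the ranking. Of the leading peaks by fold enrichment, 40 of 50 growing, 36 of 50 quiescent and 39 of 50 RB knockdown peaks lay in both other lists. The tallest of the RB knockdown list was on chromosome 2, 136349606 to 136351183, with 154-fold enrichment and 420 tags. It was followed by chromosome 3, 128799529 to 128800362 (129-fold), and chromosome 6, 20509216 to 20510555 (92.4-fold). The tallest growing peaks were on chromosome 2, 173926478 to 173929003 (52.0-fold), and chromosome 20, 35157392 to 35158493 (34.2-fold). The tallest quiescent peaks were on chromosome 4, 8355674 to 8357255 (43.8-fold), and chromosome 1, 154452509 to 154453757 (41.6-fold). Each of these 7 peaks had a partner in both other lists.

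The 100 strongest peaks of each list were mostly found in the other lists at full length, and the shares were lower among the 1000 strongest. The RB knockdown list held 98 of the 100 strongest growing peaks and 98 of the 100 strongest quiescent peaks. The quiescent list held 97 of the 100 strongest growing peaks, and the growing list 89 of the 100 strongest quiescent ones. Of the 1000 strongest the RB knockdown list held 720 growing and 891 quiescent peaks. The quiescent list held 581 of the 1000 strongest growing peaks, and the growing list 459 of the 1000 strongest quiescent ones. In the other direction, the growing list held 82 and the quiescent list 84 of the 100 strongest RB knockdown peaks, and 458 and 667 of the 1000 strongest.

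Of the tests below, those of depth, false calls at the threshold and even spread, and the comparison of reduced long peaks with all shorter ones, were chosen after their results were in view. The RB knockdown list held over 4 times as many peaks as either other list. Sequencing depth is argued against as the cause, since that library had 0.927 times the quiescent library's filtered tags. Splitting of sites by the smaller d setting is argued against as well, because joining peaks up to 1000 bp apart left a ratio of 4.04 to the quiescent list. Other effects of d on the number of calls were not tested. The median FDR of 1.21%, the lowest of the 3 lists, argues only against more false calls of the kind that exchanging ChIP and control counts. That FDR does not count pull-down without E2F7, it falls as more ChIP peaks are called, and d differed between lists. False calls of other kinds therefore stay open. A more efficient immunoprecipitation in that library stays open, because 83.2% (81.4% to 84.9%) of quiescent peaks with an FDR of at most 5% lay in its list and no second library or intact-RB senescent list was analysed here. An effect of RB loss or of senescence stays open and untested for the same reason.

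Most growing peaks (7023 of 9481) lay in neither other list, with a median of 20 tags and a median FDR of 72.8%. Those in either other list had a median of 52 tags and a median FDR of 72.1%, so the median FDR hardly separated shared from unshared peaks. Background calls may account for part of the unshared peaks. Sharing with either other list fell from 98.3% (95.04% to 99.6%) of the growing peaks with an FDR of at most 5% to 20.2% (19.4% to 21.1%) of those over 60%, and the share after shifts of 10 to 100 kb fell too, from 20.2% to 5.91%. The ratio to these shifts was 4.88 in the former and 3.42 in the latter, with 5.75 to 6.71 between. Neither prediction written in advance was met. As the cause, background calls should have given a ratio of at most 2 over an FDR of 60%, where 3.42 was found. Against them, sharing there should have been over 50% of the sharing at an FDR of at most 5%, and 20.2% lies below that. False calls spread evenly over the genome are argued against only as the source of all the unshared peaks. The autosomal ones lay on chromosomes 11, 17, 19 and 20 at 1.61 times (1.53 to 1.69) these chromosomes' share of autosomal sequence. These were the 4 autosomes densest in RB knockdown peaks outside the growing list, so the peaks tested had no part in the choice, but the rule and its bound of 1.5 were set after the densities of the lists were in view. Evenly spread false calls as a part of the unshared peaks stay open, because the ratio describes the set as a whole. Background that follows open chromatin and weak binding particular to growing cells both stay open, because peaks unshared by definition cannot be tested by overlap.

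Long peaks were shared more often than others. In the RB knockdown list 31.2% (25.6% to 37.2%) of the 263 peaks of at least 3000 bp lay in both other lists, against 2.88% of shorter ones. A candidate explanation is their low p, since shorter peaks matched on -10*log10 p were shared at 39.2% (33.2% to 45.3%). The matched peaks had a higher median fold enrichment (15.0 against 7.79) and the largest gap in -10*log10 p was 923, so the match was not close in every respect. By fold enrichment, long peaks were the stronger ones in the RB knockdown list (7.79 against 7.12 for all shorter peaks) but not in the growing (5.05 against 6.56) and quiescent lists (5.66 against 6.36). Width alone stays open. Every peak was reduced to 250 bp on either side of its summit. Long peaks were then shared at 11.03% (7.51% to 15.5%), below the matched ones (34.2%), as predicted in advance for width as the cause. That fall cannot decide, because summits spread over up to 11121 bp in the leading common regions, so the reduction itself can separate long peaks. Long peaks were not above the matched ones at full width either. After the reduction they stayed above the 1.98% of all shorter ones, a comparison chosen after the result was seen and not matched on strength. Pull-down without E2F7 at these long regions stays open, because 0 peak lists of the knockdown or IgG libraries were used.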
